A study of Homo sapiens with 12 samples.

How the data were processed

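RNA from SK-N-SH cells, an established human neuroblastoma line, was sequenced in 12 libraries that form 4 groups of 3. 1 pair of groups received the solvent DMSO or chaetocin at 50 nM, and the other pair was transfected with a control siRNA (siNC) or an siRNA against SUV39H1 (siSUV39H1), per the labels. The submitters' design text calls the replicates biological triplicates and names the silencing constructs shNC and shSUV39H1, whereas the sample labels speak of siNC and siSUV39H1. The wording of the sample labels is used here. No separate culture days or library batches are named in the labels. Total RNA was extracted with Trizol and prepared for DNBSEQ sequencing, per the labels' protocols.

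The deposited tables give, per gene and library, an RSEM-type expected count, an FPKM value and a TPM value, per the file headers. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the genome build hg38, without saying which step used which. The annotation and any read filter are not given in the sources used here. The tables hold 18739 genes, each with an Entrez identifier and a symbol, and 18574 of the identifiers were found in the RefSeq gene table for GRCh38.p14, from which the coordinates given in the results come. The deposited FPKM values and the authors' group averages were not used. The deposited TPM values served 1 alternative only. All 12 libraries were mapped to their groups by name, and 0 columns of single libraries were left unmapped.

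The expected counts were rounded to whole numbers, filtered with filterByExpr by group, scaled by TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with all 12 libraries in 1 fit and 1 mean per group. 15051 genes were tested, with 8 residual degrees of freedom and a biological coefficient of variation of 8.87%. The contrasts were chaetocin minus DMSO, siSUV39H1 minus siNC, the difference of those 2 effects, and siNC minus DMSO. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values ± their standard error, derived from the fold change and the F statistic, with n = 3 libraries per group. Levels are TMM-normalized CPM as mean ± SD, n = 3.

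27 gene lists were fixed before the data were examined, as were the tests, the other processing choices to be tried and the rule for the genes named. The lists cover H3K9 methylation, mitosis, DNA replication, p53 targets, apoptosis, redox genes, metallothioneins, the unfolded protein response, heat shock, hypoxia, cholesterol synthesis, interferon, NF-kB, adrenergic and mesenchymal neuroblastoma, neuronal differentiation, MYC targets, immediate early genes, germline genes, 4 sets of markers of other cell types, mitochondrially encoded genes, ribosomal proteins, zinc finger genes and histones. The 26 lists with at least 5 tested members were tested with camera of limma 3.58.1, a test of a list against all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The mitochondrially encoded list was not analysed here, with 0 members tested. Each list was also tested with the correlation estimated from the libraries and with fry, which asks whether a list moves on balance without comparing it with other genes. Members of a list were counted as called after adjustment over all genes and after adjustment over the list alone.

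The genes named are SUV39H1, SUV39H2, AURKA, ZC3H12A, MYC and MYCN; the 6 genes of the largest rise and the 6 of the largest fall in both main comparisons among called genes with a mean of at least 5 CPM and no overlap between the groups; the 4 largest in each direction for the difference; and, for lists with at least 3 called members, the 3 with the smallest p. Some lists were left without named members for space. Some genes that the rule takes are not reported here. Genes named outside that rule are said to have been chosen after their values were seen. A group with 0 counts in all libraries was set to a floor of 3 counts over the group, and groups with few counts have a count ratio with an exact 95% interval. These intervals and floors cover counting error only. Key genes were also compared by an exact two-sided permutation test of log2(CPM + 0.5), whose smallest possible p for 3 against 3 libraries is 0.1. Overlaps were tested with a one-sided Fisher's exact test.

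The alternatives were RLE, upper-quartile or no composition scaling, other filters for low counts, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), a 2-fold minimum, only the 6 libraries of a comparison, the replicate number as a block, and each replicate left out in turn. The same alternatives for the controls, and the removal of genes whose 3' UTR holds 1 of the 7-base sequences GTCTTCA and CGGAGAA, which were found from the expression changes themselves, were chosen after seeing the data. That removal of genes also left out the 426 tested genes with no 3' UTR searched. Alternatives written for tables with only FPKM or TPM were not needed, as counts were given. For the closing observations, 3' UTRs were searched for all 7-base sequences in 14625 of the 15051 tested genes (97.2%), using Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. These 3' UTRs came from GENCODE transcripts, with the longest taken for each gene. Sequences were chosen on a random first part of the genes and measured on the other part, in a model with 3' UTR length and base content.

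The pipeline was tested on simulated counts with known changes. Far fewer genes were changed than in the data, and counts were drawn independently for each gene. The shares called therefore do not carry over to the data, and false calls of lists among correlated genes were not tested. Library totals ran from 18004632 to 19976995 counts, and the precision at that depth was tested as follows. In the simulated chaetocin comparison, with 13966 genes, 64% of the 50 genes changed 1.5-fold were called, 90% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, along with 6 of 13766 unchanged genes. In the simulated siSUV39H1 comparison, with 13873 genes, the shares were 74%, 98%, 100% and 100%, along with 8 of 13673 unchanged genes. All 3 simulated lists that moved were called in each comparison, and 0 others were called by camera with either correlation. The search for 7-base sequences, tested on the 14625 genes of the siSUV39H1 comparison, found the planted sequence in 20 of 20 simulations at a shift of −0.17 log2, in 15 of 20 at −0.1 and in 0 of 20 without a shift.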

Results

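Gene expression was profiled in 12 RNA libraries of SK-N-SH neuroblastoma cells, 3 for each of DMSO, chaetocin, siNC and siSUV39H1. The libraries measure RNA only, so the activity of SUV39H1 and H3K9 methylation were not measured in either treatment. SUV39H1 is a histone methyltransferase that trimethylates lysine 9 of histone H3, and chaetocin is a fungal metabolite used as an inhibitor of it. Total counts were 19644426, 19976995 and 19944011 in the DMSO libraries, 18235528, 18177124 and 18004632 with chaetocin, 19748841, 19875841 and 19799113 with siNC, and 19687556, 19672979 and 19595821 with siSUV39H1. Counts above 0 were found for 17729 ± 32.3 genes with chaetocin (mean ± SD, n = 3), against 16264 ± 39.8 with DMSO, 16196 ± 68.2 with siNC and 16202 ± 59 with siSUV39H1. No 2 libraries of a group were copies of each other, as their counts differed by 3.51 to 18.8 times the counting variance. The first principal component held 79.6% of the variance and set the chaetocin libraries apart from the other 9.

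The first question was whether the target of the knockdown fell, and how the genes named with it in the study's title, AURKA and ZC3H12A, responded. SUV39H1 (chromosome X, 48695554 to 48709016, hg38) fell from 17.5 ± 1.05 CPM with siNC to 5.76 ± 0.3 with siSUV39H1, a log2 change of −1.60 ± 0.11 that was seen in each of the 3 libraries. Chaetocin lowered the same transcript from 21.5 ± 2.7 to 7.65 ± 0.195 CPM (−1.49 ± 0.11). AURKA (chromosome 20, 56369390 to 56392215), the mitotic kinase Aurora A, fell with both treatments. It went from 34.2 ± 1.48 to 21.7 ± 2.17 CPM with chaetocin (−0.65 ± 0.10) and from 29.7 ± 0.982 to 19.9 ± 2.28 CPM with siSUV39H1 (−0.58 ± 0.10). These falls were near the medians of the mitosis list, of which AURKA is a member (−0.72 with chaetocin and −0.53 with siSUV39H1). ZC3H12A (chromosome 1, 37474580 to 37484377), which encodes the ribonuclease MCPIP1, rose 15.4-fold with chaetocin, from 5.06 ± 0.892 to 78.1 ± 6.32 CPM, and 2.01-fold with siSUV39H1, from 18 ± 1.19 to 36.1 ± 5.83 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p for SUV39H1, AURKA and ZC3H12A was 4.12e-09, 1.62e-05 and 7.54e-13 with chaetocin and 5e-08, 0.0003 and 1.5e-05 with siSUV39H1. For each of these genes the treated libraries did not overlap the controls in either comparison, where the exact permutation p is 0.1, the smallest that 3 against 3 libraries allow. The paralog SUV39H2 was not detectably different. Its log2 change was 0.034 ± 0.16 with chaetocin (adjusted p = 0.846, edgeR) and 0.38 ± 0.16 with siSUV39H1 (adjusted p = 0.0771, and 0.0398 without siNC replicate 3).

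**Figure D1:**
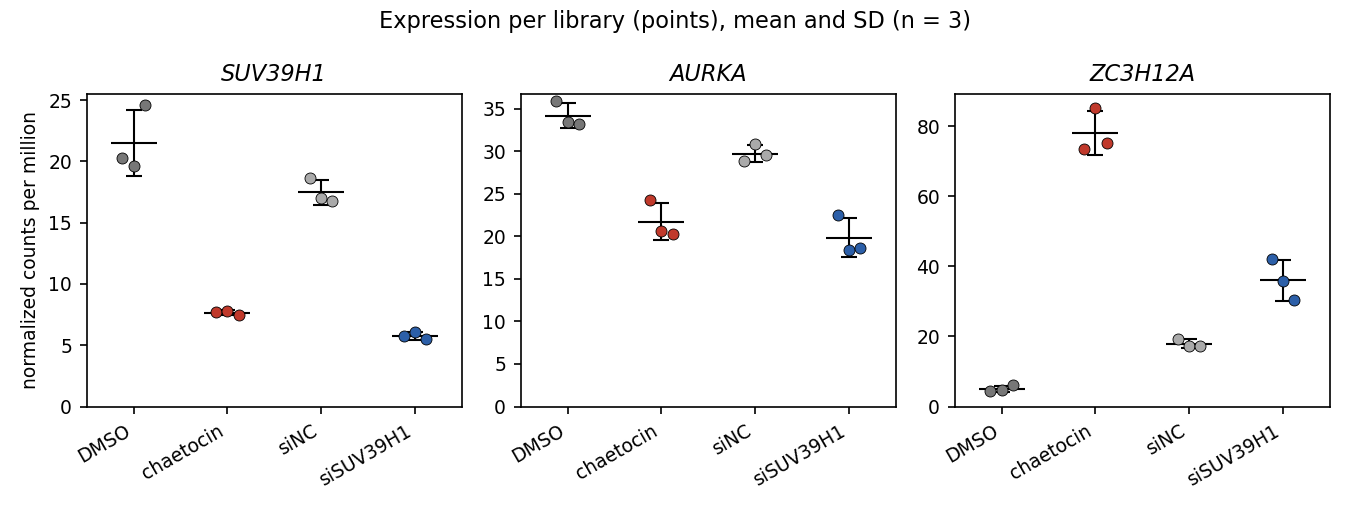
Normalized CPM of SUV39H1, AURKA and ZC3H12A in each of the 12 libraries (points), with the mean (long bar) and SD (error bars) of each group of 3. SUV39H1 and AURKA are lower and ZC3H12A is higher in both treated groups than in their own controls, and ZC3H12A is also higher in siNC (18 CPM) than in DMSO (5.06 CPM).

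The comparison of chaetocin with DMSO asked what the inhibitor changed. Treated cells gained transcripts of interferon, NF-kB and redox responses and lost those of the noradrenergic neuroblast. All 21 interferon-stimulated genes tested rose, with a median log2 change of 6.22. They include the antiviral effectors MX1 (7.54 ± 0.09) and OAS3 (6.16 ± 0.11), and OAS2, whose counts of 6 in DMSO and 5618 with chaetocin give a ratio of 924 (95% interval 424 to 2520). All 19 NF-kB and inflammatory cytokine genes rose (median 5.11), among them IL1B (9.14 ± 0.16), the NF-kB subunit NFKB2 (4.28 ± 0.07) and IER3 (5.74 ± 0.10). All 20 redox genes, most of them targets of the transcription factor NRF2, rose (median 1.83), led by heme oxygenase HMOX1, which went from 14.7 to 1486 CPM (6.66 ± 0.12). In that list the glutathione synthesis gene GCLM rose by 3.66 ± 0.09 and PIR by 3.07 ± 0.09. Of 18 adrenergic neuroblastoma genes, 17 fell and 1 rose (median −3.87): the noradrenaline transporter SLC6A2 (−7.23 ± 0.16), the noradrenaline-forming enzyme DBH (−6.28 ± 0.12) and the lineage regulator PHOX2A (−5.57 ± 0.12) were among those that fell.

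Among single genes with chaetocin, the largest rises among the genes named were of genes near 0 counts in DMSO, most of them chemokines and cytokines. CXCL10 was at least 996-fold higher, UBD at least 695-fold and TNF at least 244-fold, each against a floor of 3 counts over the 3 DMSO libraries. CXCL11 rose from 1 to 4689 counts, a ratio of 4630 (830 to 183000), CCL20 from 1 to 3751 counts (3700, 664 to 146000) and the ion cotransporter gene SLC12A7 from 6 to 8743 counts (1440, 660 to 3920). Large falls, next to SLC6A2 and DBH, were those of PRRT4 (−7.31 ± 0.17) and the channel subunit gene CACNG4 (−6.54 ± 0.13). MYC fell from 31.9 ± 3.53 to 4.91 ± 0.787 CPM (−2.70 ± 0.12). MYCN fell from 183 to 5 counts, which is 37.1-fold lower with a 95% interval of 15.6 to 116.

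Most members of the neuronal, DNA replication and mitosis lists also fell with chaetocin. Of 24 neuronal differentiation genes 20 fell and 3 rose (median −2.95, adjusted p = 0.0727 with an estimated correlation), with STMN2 at −5.54 ± 0.13, RTN1 at −4.28 ± 0.12 and GAP43 at −3.30 ± 0.09. Of 30 DNA replication genes 28 fell (median −0.86, adjusted p = 0.239 with an estimated correlation), including CDC45 (−2.02 ± 0.12), RRM2 (−1.69 ± 0.08) and TYMS (−1.24 ± 0.07). Of 30 mitosis genes 24 fell and 1 rose (median −0.72, adjusted p = 0.222 with an estimated correlation), including FOXM1 (−2.22 ± 0.09), BIRC5 (−1.79 ± 0.08) and PLK1 (−1.56 ± 0.09). Among 23 genes of the ATF4 and unfolded protein response 17 fell and 5 rose (adjusted p = 0.405 with an estimated correlation): the endoplasmic reticulum chaperones CALR (−2.29 ± 0.08) and HSPA5 (−1.65 ± 0.06) fell, whereas the stress factor ATF3 rose (4.53 ± 0.17). Cholesterol synthesis genes fell in 13 of 19 cases and rose in 3 (adjusted p = 0.0727 with an estimated correlation), with DHCR7 at −1.75 ± 0.08. Mesenchymal neuroblastoma genes fell in 14 of 23 cases and rose in 9 (adjusted p = 0.174 with an estimated correlation), with COL3A1 (−3.42 ± 0.09) and TWIST1 (−2.42 ± 0.07) lower. Ribosomal protein genes fell in 62 of 83 cases and rose in 1 (median −0.35, adjusted p = 0.722 with an estimated correlation, and 0.0507 with the preset one without DMSO replicate 3). With library totals only, 44 of them fell and 1 rose (median −0.20).

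Stress and death genes rose in part with chaetocin. Of 24 p53 target genes 15 rose and 5 fell (median 0.60, adjusted p = 0.103 with an estimated correlation), with the cytokine GDF15 (3.76 ± 0.11) and PLK3 (2.25 ± 0.07) higher and TP53I3 (−1.94 ± 0.09) lower. Of 27 apoptosis regulators 18 rose and 5 fell (median 0.86, adjusted p = 0.0662 with an estimated correlation), including the BH3-only gene PMAIP1 (2.09 ± 0.09), the survival gene BCL2A1 (4.29 ± 0.16) and the death receptor TNFRSF10A (2.91 ± 0.13). Heat shock genes rose in 10 of 16 cases and fell in 3 (adjusted p = 0.103 with an estimated correlation). With the preset one the call was lost without DMSO replicate 1 (0.0561) or 3 (0.0503). Examples are DNAJA1 at 1.90 ± 0.08, CRYAB at −2.78 ± 0.10 and HSPA1A at 2.95 ± 0.09, the last uncertain because HSPA1B is nearly identical. Immediate early genes rose in 14 of 22 cases and fell in 8 (adjusted p = 0.222 with an estimated correlation), with NR4A2 (5.30 ± 0.14) and JUNB (3.00 ± 0.10) higher beside IER3. Zinc finger genes rose in 273 of 484 cases and fell in 72 (268 and 71 adjusted over the list alone, median 0.54, adjusted p = 0.524 with an estimated correlation, and 0.0506 with the preset one and library totals only). Markers of other cell types rose as well: 9 of 10 epithelial markers, 7 of 7 blood cell markers and 4 of 6 endothelial markers, with 1 endothelial marker lower. With an estimated correlation their adjusted p = 0.0727, 0.0727 and 0.103. Examples are ELF3 (5.46 ± 0.20), KRT7 (2.79 ± 0.18) and KRT8 (0.89 ± 0.09), PTPRC (4.81 ± 0.20), FCER1G (4.68 ± 0.26) and CSF1R (2.44 ± 0.20), and VWF (4.20 ± 0.23) and ERG, whose count ratio was 247 (113 to 675).

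In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 11965 of 15051 genes with chaetocin, 6180 higher and 5785 lower, and 3279 and 2408 of them changed at least 2-fold. Camera called 19 of 26 lists, 11 higher and 8 lower. With an estimated correlation, 4 of those calls held: interferon (adjusted p = 0.00545), NF-kB (0.00545), redox (0.0129) and adrenergic genes (0.0424). The other 15 did not, with the values given above. Camera did not call 7 lists. Among them were the genes of H3K9 methylation, of which 8 of 20 rose and 6 fell, with the corepressor TRIM28 at 2.18 ± 0.08 and KDM1A at −1.37 ± 0.07. The others were metallothioneins (5 of 8 rose, 2 fell), hypoxia (11 of 20 rose, 7 fell), and MYC targets (6 of 23 rose, 13 fell), along with germline genes (7 of 13 rose, 5 fell), Schwann and glial markers (3 of 7 rose, 2 fell) and histones (25 of 34 rose, 5 fell). Adjusted over the list alone, the counts of members were the same in every list with chaetocin except the zinc fingers. Scaling by library totals only raised the median of all genes by 0.15 log2, so changes of that size depend on the scaling.

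The comparison of siSUV39H1 with siNC asked what changed with the lowering of SUV39H1 mRNA, and fewer genes changed at least 2-fold (512 against 5687 with chaetocin). Mitotic genes fell: 19 of 30 were lower and 0 higher (median −0.53, 22 lower adjusted over the list alone, adjusted p = 0.297 with an estimated correlation), including the kinesin KIF20A (−0.88 ± 0.08), the kinase PLK1 (−0.88 ± 0.09) and cyclin CCNB1 (−0.76 ± 0.08). In the hypoxia list 9 of 20 genes fell and 2 rose (11 and 3 adjusted over the list alone, adjusted p = 0.351 with an estimated correlation), with LDHA at −1.43 ± 0.07, PDK1 at −1.10 ± 0.12 and HK2 at −0.92 ± 0.09. Of 83 ribosomal protein genes 53 fell and 1 rose (median −0.27, 69 and 2 adjusted over the list alone, adjusted p = 0.615 with an estimated correlation), among them RPL22L1 (−0.86 ± 0.13) and RPS27L (−0.44 ± 0.08). Adrenergic genes rose slightly, 6 of 18 with 0 lower (median 0.27, 11 and 0 adjusted over the list alone, adjusted p = 0.615 with an estimated correlation), among them SLC6A2 (0.64 ± 0.09), HAND2 (0.45 ± 0.08) and TBX2 (0.42 ± 0.07). This rise started from a lowered control, as the median of the list in siNC against DMSO was −0.96.

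Among single genes with siSUV39H1, the protease-like gene PRSS35 rose most of the genes named (2.43 ± 0.12, from 6.33 to 34.2 CPM). It was followed by the cytochrome CYP1B1 (1.95 ± 0.17), LGSN (1.80 ± 0.22), the synaptic organizer CBLN2 (1.70 ± 0.11), the tropomyosin TPM4 (1.69 ± 0.07) and the syntaxin STX12 (1.65 ± 0.07). The neuronal pentraxin NPTX1 fell most of them (−3.18 ± 0.15, from 22.8 to 2.51 CPM). Others that fell were GALNT15 (−2.34 ± 0.14), TMEM158 (−2.15 ± 0.14) and IGSF8 (−2.12 ± 0.09). For several of these genes siNC also stood apart from DMSO, so that the fold against siNC is larger than the distance from DMSO. Levels in DMSO, siNC and siSUV39H1 were 17.7, 6.33 and 34.2 CPM for PRSS35, 12.3, 7.19 and 27.8 for CYP1B1, 10.7, 7.49 and 24.3 for CBLN2, 742, 280 and 902 for TPM4 and 42.6, 21.2 and 66.6 for STX12. They were 5.7, 22.8 and 2.51 CPM for NPTX1 and 36.7, 73.1 and 16.5 for TMEM158. MYC fell slightly (−0.43 ± 0.11, adjusted p = 0.00598 by edgeR, and 0.0597 by limma-trend on TPM). MYCN, with 183 counts in DMSO, rose from 60 counts in siNC to 111 with siSUV39H1 (0.85 ± 0.30, edgeR adjusted p = 0.0379). That call was lost with DESeq2 (0.0536), with the replicate number as a block (0.052), without siNC replicate 1 (0.108) or 3 (0.131), and without siSUV39H1 replicate 1 (0.0953), 2 (0.0695) or 3 (0.0563).

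With siSUV39H1 neuronal genes rose in 7 of 24 cases and fell in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.615 with an estimated correlation), with the granin SCG2 (1.04 ± 0.09), DCX (0.98 ± 0.14) and NCAM1 (0.58 ± 0.08) higher. The median of this list in siNC against DMSO was −0.78. Of 24 p53 targets 13 rose and 4 fell (15 and 4 adjusted over the list alone, adjusted p = 0.351 with an estimated correlation), with SESN2 (0.81 ± 0.08) and FDXR (0.78 ± 0.08) higher and TP53INP1 (−1.12 ± 0.11) lower. Of 23 genes of the ATF4 list 8 rose and 2 fell (adjusted p = 0.615 with an estimated correlation). With the preset one the call was lost without siNC replicate 3 (0.123) or siSUV39H1 replicate 1 (0.193). The members that rose include CHAC1 at 0.64 ± 0.09 and ATF4 itself at 0.37 ± 0.06 beside SESN2. DNA replication genes fell in 13 of 30 cases and rose in 1 (adjusted p = 0.615 with an estimated correlation, and 0.0524 with the preset one without siNC replicate 2), with GINS1 (−0.81 ± 0.13), TK1 (−0.67 ± 0.10) and UHRF1 (−0.59 ± 0.08) lower. MYC target genes fell in 13 of 23 cases and rose in 2 (adjusted p = 0.615 with an estimated correlation), with NOP16 at −0.47 ± 0.08 and NOLC1 at 1.24 ± 0.09 beside LDHA. Of 7 Schwann and glial markers 4 fell and 0 rose (median −0.81, adjusted p = 0.297 with an estimated correlation), including PMP22 (−0.89 ± 0.07), ERBB3 (−0.93 ± 0.17) and PLLP (−0.81 ± 0.16). Zinc finger genes rose in 84 of 484 cases and fell in 19 (75 and 16 adjusted over the list alone, adjusted p = 0.615 with an estimated correlation), with ZNF664 (1.57 ± 0.10), ZNF629 (1.06 ± 0.09) and ZNF875 (0.76 ± 0.09) higher. The NF-kB list did not follow ZC3H12A: 3 of its 19 genes rose and 5 fell, with CCL2 (−0.59 ± 0.09), RELB (−0.61 ± 0.07) and TNFAIP2 (−0.79 ± 0.11) lower. In the interferon list 1 of 21 genes rose and 2 fell.

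In all, edgeR called 5109 of 15051 genes with siSUV39H1, 2310 higher and 2799 lower, and 172 and 340 of them changed at least 2-fold. The balance of directions depended on unit and scaling, with 3318 higher and 1941 lower by limma-trend on TPM and 2800 and 2549 with library totals only. Camera called 11 of 26 lists with the preset correlation, 5 higher and 6 lower. With an estimated correlation 0 were called by camera (3 had an unadjusted p under 0.05, and fry called 17). An alternative chosen after seeing the data left out the genes that hold 1 of 2 7-base sequences found from them, and those with no 3' UTR searched. In it the preset-correlation calls for hypoxia (adjusted p = 0.0936), MYC targets (0.0678) and the ATF4 list (0.154) were lost. In the lists that camera did not call, members called higher and lower numbered 3 and 3 of 20 for H3K9 methylation, 3 and 7 of 27 for apoptosis, 4 and 4 of 20 for redox, 0 and 2 of 8 for metallothioneins, and 3 and 1 of 16 for heat shock genes. The numbers were 1 and 5 of 19 for cholesterol synthesis, 5 and 7 of 23 for mesenchymal, 3 and 7 of 22 for immediate early and 0 and 3 of 13 for germline genes. They were 2 and 1 of 10 for epithelial, 0 and 1 of 7 for blood cell, 0 and 1 of 6 for endothelial and 4 and 3 of 34 for histone genes.

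**Figure D2:**
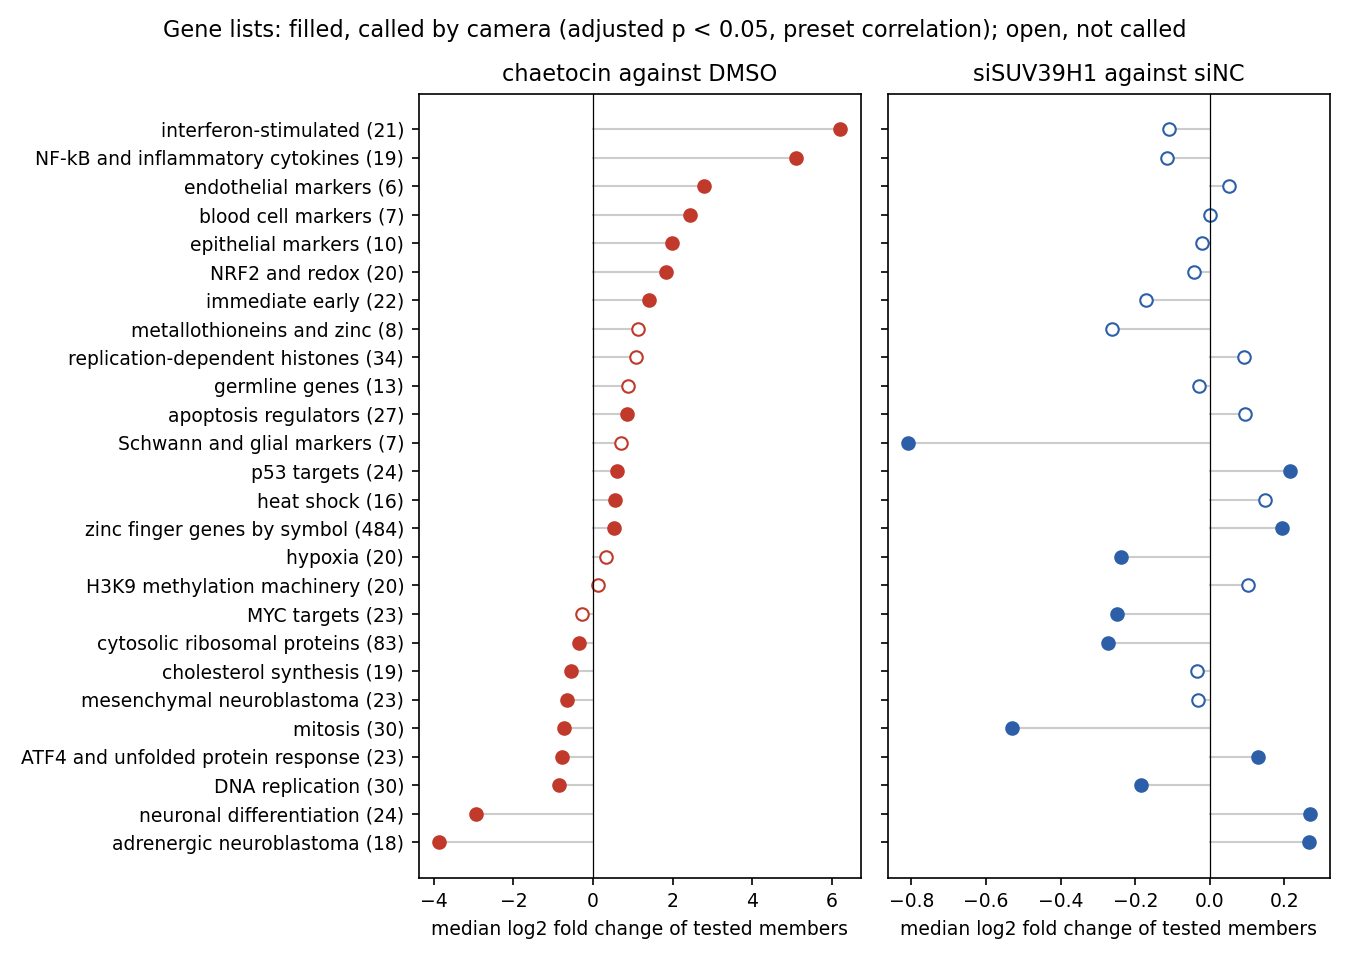
Median log2 fold change of the tested members of 26 gene lists (their number in brackets), with chaetocin against DMSO on the left and siSUV39H1 against siNC on the right. The horizontal axes have different ranges, filled points passed camera with the preset correlation, and the interferon list stands at 6.22 on the left and −0.11 on the right.

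The next question was how far the inhibitor and the knockdown changed the same genes. SLC6A2 and DCX, genes of noradrenaline uptake and neuronal migration, fell with chaetocin and rose with siSUV39H1 against siNC, while SUV39H1 and AURKA fell in both. The rise of SLC6A2 started from a lowered control, with 89.2 CPM in DMSO, 43.7 in siNC and 68.1 with siSUV39H1. The difference of the effects was −7.87 ± 0.19 for SLC6A2, −7.59 ± 0.20 for PRRT4 and −7.09 ± 0.28 for DCX. CCL20, CXCL11 and UBD responded to chaetocin but not in the same way to siSUV39H1 (adjusted p of the difference 6.69e-10, 7.41e-08 and 2.78e-06, edgeR). So did MLC1, with 2 counts in DMSO and 2722 with chaetocin (ratio 1340, 371 to 11100). The adjusted p of its difference was 0.00146 by edgeR, and that call was lost without siNC replicate 3. Counts in siNC and with siSUV39H1 were 45 and 22 for CCL20, 10 and 10 for CXCL11, 4 and 0 for UBD and 1 and 0 for MLC1. With so few counts the response to siSUV39H1 cannot be estimated for UBD and MLC1. The ZC3H12A response was 2.94 ± 0.18 log2 larger with chaetocin (adjusted p = 1.33e-09, edgeR). Its controls stood apart, with 5.06 CPM in DMSO and 18 in siNC, against 78.1 with chaetocin and 36.1 with siSUV39H1. Part of that difference is therefore the higher level in siNC. For SUV39H1 the difference was 0.11 ± 0.16 (adjusted p = 0.542) and for AURKA −0.069 ± 0.14 (adjusted p = 0.672, edgeR), and the AURKA difference changed sign, to 0.043 with library totals only and 0.018 without siSUV39H1 replicate 1.

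Both treatments lowered 1392 genes, against 1076 for independent lists (n = 5785 and 2799 of 15051; one-sided Fisher's exact p = 1.37e-41), and raised 828, against 948.5 (p = 1). By the same Fisher's exact test, opposite calls were 904 genes higher with chaetocin and lower with siSUV39H1, against 1149 (p = 1), and 1037 lower and higher, against 887.9 (p = 3.42e-12). Genes lowered by chaetocin were thus over-represented among siSUV39H1 calls of both directions (1.29 and 1.17 times). Those raised by chaetocin were under-represented in both (0.873 and 0.787). The test takes all genes as equally likely to be called, so its p-values do not measure a shared direction alone. Of the 4161 genes called in both, 53.4% had the same direction, and across all genes, which are not independent replicates, the correlation of the fold changes was −0.015 (Pearson) and 0.035 (Spearman). At a 2-fold minimum, Fisher's exact test gave 64 genes higher in both, against 37.47 (p = 2.66e-06), and 58 lower in both, against 54.4 (p = 0.317). By the same Fisher's exact test, 130 were higher with chaetocin and lower with siSUV39H1, against 74.07 (p = 2.55e-12), and 45 lower and higher, against 27.52 (p = 0.000415). The difference of the effects was called for 10171 genes by edgeR, 5104 of them positive and 5067 negative. Camera called 11 of 26 lists for the difference. The call held with an estimated correlation for NF-kB (median 4.65, adjusted p = 0.00441), interferon (6.30, 0.00906), redox (1.89, 0.0123) and adrenergic genes (−4.17, 0.0182). The medians of siNC against DMSO, 1.83 for NF-kB and −0.96 for adrenergic genes, bear on the baseline of these differences. With an estimated correlation the adjusted p was 0.0549 for neuronal (median −3.37), 0.0835 for apoptosis (0.64) and 0.147 for metallothionein genes (1.21). The call was also lost for immediate early (1.16, 0.237), mesenchymal (−0.43, 0.283), ATF4 (−1.02, 0.314) and DNA replication genes (−0.72, 0.403). For mitosis the difference was not called (−0.20, adjusted p = 0.281 with the preset correlation). The metallothionein call with the preset correlation was also lost with RLE scaling (0.0538) and without DMSO replicate 1 (0.0568), chaetocin replicate 3 (0.054), siNC replicate 1 (0.0518) or siSUV39H1 replicate 2 (0.0545).

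The control groups, which were handled differently, also differed. Cells given siNC had higher NF-kB genes than cells given DMSO (17 of 19 rose, 18 adjusted over the list alone, median 1.83). They also had higher p53 targets (18 of 24 rose and 2 fell, 0.56) and higher apoptosis regulators (12 of 27 rose and 3 fell, 13 and 3 adjusted over the list alone, 0.30). Adrenergic genes were lower (17 of 18 fell, −0.96), as were 20 of 24 neuronal genes (−0.78), 20 of 30 mitosis genes (21 adjusted over the list alone, −0.52) and 25 of 30 DNA replication genes (27, −0.49). ZC3H12A was 1.83 ± 0.14 higher in siNC (adjusted p = 2.76e-07, edgeR) and MYCN was lower, 60 against 183 counts (−1.63 ± 0.28, adjusted p = 0.000375). SUV39H1 was lower in siNC (−0.30 ± 0.10), with adjusted p = 0.0316 by edgeR. That call was lost without DMSO replicate 3 (0.17, at −0.19), siNC replicate 2 (0.0724) or siNC replicate 3 (0.105), and under several other alternatives given below. AURKA was at −0.20 ± 0.10 (adjusted p = 0.119). EdgeR called 5293 genes between the controls, 2552 higher and 2741 lower in siNC, with 758 changed at least 2-fold, and camera called 10 of 26 lists. The balance of directions turned with library totals only, to 2831 higher and 2606 lower. With an estimated correlation the calls for NF-kB (adjusted p = 0.00827), p53 (0.0112), apoptosis (0.0413) and adrenergic genes (0.0413) held. Those for neuronal (0.0537), mitosis (0.0728), DNA replication (0.138), redox (0.451), ATF4 (0.451) and immediate early genes (0.479, and 0.0705 with the preset correlation without DMSO replicate 2) did not. Solvent, transfection and any difference in culture or batch between the experiments cannot be told apart here, since each experiment has its own control.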

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

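The tests of explanations for the ZC3H12A rise were chosen after the result was seen, whereas the test of the difference between the effects was not. Each result here stands out because the response to chaetocin and the response to siSUV39H1 differed by that test. 1941 genes were called in opposite directions with the difference itself called by edgeR. Of them, 904 were higher with chaetocin and lower with siSUV39H1, against 1149 for independent lists, and 1037 were the reverse, against 887.9. These are all the genes with opposite calls, so the called difference removed none and adds no support of its own. ZC3H12A rose in both, by 2.94 log2 more with chaetocin, though its control level was 1.83 log2 higher in siNC than in DMSO. MYC fell in both, with a difference of −2.27, while MYCN fell with chaetocin and was called higher with siSUV39H1 in a call that DESeq2 did not make (0.86, adjusted p = 0.0536), with a difference of −5.97. The medians of the difference were −1.02 for the ATF4 and unfolded protein response list (adjusted p = 0.314 with an estimated correlation), −4.17 for the adrenergic list (0.0182) and −3.37 for the neuronal list (0.0549). The adrenergic and neuronal lists and MYCN were lower in siNC than in DMSO (−0.96, −0.78 and −1.63), so their rises with siSUV39H1 started from a lowered control.

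The rise of ZC3H12A, an NF-kB target, was weighed against a general NF-kB response and against an action of the control siRNA. With siSUV39H1 the NF-kB list did not rise with it, with a median of −0.115 and 3 of 19 genes higher and 5 lower. This argues against a rise shared by the list over its level in siNC. It cannot exclude NF-kB as a cause for ZC3H12A itself. The list was already higher in siNC than in DMSO (median 1.83), and an action of the ribonuclease MCPIP1 on its transcripts was not tested. A lowering of ZC3H12A by the control siRNA cannot be told apart: its level in siNC was 1.83 log2 above DMSO, but these controls also differ by transfection, which could hide a lowering. With chaetocin the rise of ZC3H12A may be part of a general NF-kB response, whose list had a median of 5.11. What also stays open with siSUV39H1 is the loss of SUV39H1 itself and an unintended action of the siSUV39H1 construct, which 1 knockdown construct cannot tell apart.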

How the results depend on the processing

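The alternatives for the controls and the removal of genes that hold GTCTTCA or CGGAGAA, 7-base sequences found from the data, were chosen after seeing the data. SUV39H1, AURKA and ZC3H12A kept direction and call in both main comparisons under every alternative run for single genes, from −1.64 to −1.54 for SUV39H1 and from 0.88 to 1.12 for ZC3H12A over the left-out libraries with siSUV39H1. The 2-fold minimum was run for counts of genes only, and AURKA, at −0.65 and −0.58, lies under it. Of 4749 values for 269 results on named genes, 4721 kept their side of the threshold, 27 lost their call and 1 gained one, and 0 called values changed direction. Among uncalled values the sign changed for SUV39H2 with chaetocin (without a filter, without DMSO replicate 3 and without chaetocin replicate 2) and for the AURKA difference (−0.069, and 0.043 with library totals only and 0.018 without siSUV39H1 replicate 1). Of 1325 values for 104 results on lists, 1209 kept their side of the threshold, 58 lost a call and 58 gained one. Directions of uncalled lists were not counted. A 2-fold minimum, which by construction removes small changes, left 5687 genes with chaetocin, 512 with siSUV39H1, 5410 for the difference, 758 between the controls and 122 changed the same way by both treatments. With an estimated correlation camera called 4 lists with chaetocin, 0 with siSUV39H1 (3 at an unadjusted p under 0.05), 4 for the difference and 4 between the controls. Fry, which does not compare a list with other genes, called 26 of 26 with chaetocin, 17 with siSUV39H1, 22 for the difference and 20 between the controls. The SUV39H1 difference between the controls was −0.27 with library totals only (adjusted p = 0.0537), −0.22 by limma-trend on TPM (0.121), −0.29 with the replicate block (0.0705) and −0.30 in the 6 libraries alone (0.0581), and ran from −0.37 to −0.19 over the left-out libraries. The cause was not tested. Leaving out 1 library gave 11500 to 11821 genes with chaetocin, 3868 to 5463 with siSUV39H1, 9619 to 10241 for the difference, 4167 to 5425 between the controls and 1656 to 2623 changed the same way. The replicate block gave 4430 genes with siSUV39H1, and replicate numbers do not pair the libraries, since 1 of 6 same-number correlations was over 0.1 (−0.269 to 0.16). Without genes that hold either sequence or had no 3' UTR searched, 8 lists were called with siSUV39H1, and hypoxia (0.0936), MYC targets (0.0678) and the ATF4 list (0.154) were not. Whether the smaller number of genes alone would lose these calls was not tested. In simulations at the depth of these libraries 64% and 74% of 1.5-fold changes were called. Far fewer genes changed there than in the data, which makes the adjusted threshold stricter, so these shares do not carry over. How many small changes were missed in the data is not known.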

Other observations

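The genes, families and tests of explanations in this part were chosen after the results were seen, except the test of read-through, which was set out before its result. Of genes outside the lists, the following rose with chaetocin, with no test of them as a group: the peptide transporter subunits TAP1 (3.43 ± 0.08) and TAP2 (3.73 ± 0.06), and the immunoproteasome subunits PSMB9 (3.87 ± 0.12) and PSMB8 (1.78 ± 0.09). So did the MHC class I activator NLRC5 (2.45 ± 0.11), the checkpoint ligand CD274 (4.65 ± 0.17), the transcription factor IRF1 (4.73 ± 0.09) and the chemokine CCL5 (6.84 ± 0.11). With siSUV39H1 several of them fell, namely TAP2 (−0.56, edgeR adjusted p = 4.74e-06), PSMB9 (−0.73, 0.00039), NLRC5 (−0.68, 0.000319), CD274 (−0.77, 0.00462) and IRF1 (−0.33, 0.00524), while TAP1 was at −0.10 (0.289), PSMB8 at 0.020 (0.892) and CCL5 at 0.062 (0.809).

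Gene families formed by symbol add to the lists, with 271 families of at least 8 tested genes. With chaetocin 9 of 10 CXCL chemokines rose and 1 fell (median 8.78), 9 of 10 CCL chemokines rose (4.47) and all 10 SERPINB protease inhibitors rose (2.11), as did 20 of 31 CFAP genes of cilia and flagella, with 2 lower (1.03). Among ADAMTS metalloproteases 11 of 15 fell and 2 rose (−2.0), and among PCDHB protocadherins 13 of 15 fell (−1.26). With siSUV39H1 8 of 14 IFT genes of ciliary transport rose and 5 of 8 TUBB tubulins fell. Camera called 17 families with chaetocin and 5 with siSUV39H1 at the preset correlation, and 0 in either with an estimated correlation, where 22 and 6 had an unadjusted p under 0.05.

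Genes with the 7-base sequence GTCTTCA in the 3' UTR were lower with siSUV39H1. The sequence was chosen on 1 part of the genes, and in the other part its 1096 genes were shifted by −0.16 log2, the lowest of 16042 sequences (permutation p = 0.0001, the smallest that 10000 draws can give), which may reflect pairing of the siRNA's seed with mRNAs. Against base composition or 3' UTR length as the cause, 0.0% of the other sequences among the 420 of the same bases shifted as far. Against the fall of SUV39H1 mRNA alone, chaetocin shifted the same 1096 genes by −0.0059 ± 0.0399 log2. Over all 2158 genes with GTCTTCA in the 3' UTR, including the part used to choose it, the chaetocin shift was 0.0059 ± 0.028. Such sites in the members' own 3' UTRs are argued against as the only cause of the fall of the mitosis list, whose 27 members without a site had a median of −0.48. Coding sequences and partial matches were not checked in these members. Over all genes searched, the 2156 with GTCTTCA in the coding sequence were shifted by −0.12 log2 with siSUV39H1. The 2188 with GTCTTCT in the 3' UTR were shifted by −0.085. An action of the construct on mitotic genes through such matches stays open. AURKA holds 1 site and 12 members without a site fell at least as far, so a share of its fall from that site stays open. The siRNA sequences are not given in the sources used here, and GTCTTCA occurs once in the SUV39H1 mRNA, at position 1193 of 2871, where 16% would be the chance of any such match.

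The sequence CGGAGAA was chosen the same way, as the one whose genes were highest with siSUV39H1 in the first part. In the other part its 194 genes were shifted by 0.093 log2 with siSUV39H1 against siNC (permutation p = 0.0046), by −0.10 in siNC against DMSO and by −0.008 ± 0.043 in siSUV39H1 against DMSO, so its shift goes with the siNC group. No explanation was tested for it.

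Genes near 0 counts in DMSO were counted with chaetocin: of 2891 genes with at most 3 counts over the DMSO libraries, 981 (33.9%) reached at least 10 with chaetocin and 36 in siNC, and with depth thinned to 18004591 counts the chaetocin libraries still held 17709 ± 25.2 genes against 16162 ± 36.8 in DMSO. An even background over transcripts, such as genomic DNA, is argued against as the only source, since 3.77 times as many genes reached 10 counts as a Poisson background by transcript length gives. Genes that truly rose would also give such an excess, so a background beside them stays open. Of 2721 such genes with a transcript length, 2497 were above 0 counts with chaetocin. The median of the genes near 0 in DMSO was 5 counts with chaetocin, and that of the genes near 0 in siNC was 0 with siSUV39H1. The fall of SUV39H1 mRNA alone is argued against, since of the 2993 genes with at most 3 counts over the siNC libraries, a set of their own, 41 (1.37%) reached 10 counts with siSUV39H1. For read-through from an active gene upstream on the same strand, 22.5% of the genes that reached 10 counts had such a gene within 50 kb. Of the others 18.3% had one, a difference of 4.1 points (95% interval 0.9 to 7.3, two-sided Fisher's exact p = 0.0115). The rule set before the result took at least 10 points as read-through and under 5 points as against it. The difference lies under 5 points, but its interval reaches above that limit, so a share from read-through stays open. Loss of H3K9 methylation by the inhibitor itself was not tested and also stays open.

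Other splits of the libraries were counted. For each pair of groups there are 10 splits of the 6 libraries, too few for a share under 0.05: 1 of 10 gave as many genes for chaetocin (11965 by edgeR, 0 in the highest other split, which had 182 at an unadjusted p under 0.05), 1 of 10 for siSUV39H1 (5109 and 0, with up to 3048 unadjusted) and 1 of 10 between the controls (5293 and 0, with up to 1554 unadjusted). For lists called by camera with the preset correlation, 1 of 10 splits gave as many with chaetocin (19, highest other 17), 1 of 10 with siSUV39H1 (11, highest other 9) and 5 of 10 between the controls (10, highest other 13). For the difference 60 of 200 splits within both experiments were drawn: 2 of 60 gave as many genes (10171, highest other 10209) and 1 of 60 as many genes changed the same way (2220 by edgeR, and 0 in the others). Neither count can exclude chance. The number of genes followed the chaetocin groups alone, with 8344 to 10209 in the other drawn splits that keep them, and the number changed the same way has to be 0 wherever a split of either pair calls 0 genes. For lists of the difference 31 of 60 splits gave as many (11, highest other 18), so chance cannot be excluded for that number.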
